A study of Caenorhabditis elegans with 2 samples.

How the data were processed

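The series is a chromatin immunoprecipitation and sequencing (ChIP-seq) experiment on Caenorhabditis elegans. TBX-2, a T-box transcription factor, was expressed from an integrated transgene as a fusion with green fluorescent protein and a FLAG tag at its C-terminus, in a strain that also carries a mutation of unc-119, and chromatin was precipitated with an antibody against the fluorescent protein. Embryos of hermaphrodites were collected 3.5 h after synchronization by bleaching, per the labels, and 2 biological replicates were made. There was 1 group and no second condition, so the comparisons are between the 2 replicates, between peaks and the rest of the genome, and between groups of genes.

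The authors called peaks separately on each replicate and on the pooled alignments of both, each against a control library, per the labels' accompanying file lists. These 3 lists are relaxed: they hold peaks together with background. The optimal set is labelled as the pooled peaks that passed a threshold on the irreproducible discovery rate. Not every optimal peak was found in both replicates: 5 overlapped no peak of the relaxed list of replicate 2. The aligner, the peak caller and the threshold are not given in the sources used here, and read depth per library is unknown. Each deposited list gives a peak signal, which is the authors' own value per peak on a scale that differs between lists. That signal was used to rank, describe or filter peaks within a list. Between lists it was used only to correlate and plot the replicates. The lists also give the -log10 of a q-value as deposited by the authors. It stood at its highest value, 2.976, in every optimal peak and was not used to rank. Lists on the ce11 build were used throughout and lists on ce10 as an alternative, with no conversion of coordinates. No ce11 peak ended past its chromosome in the WBcel235 assembly, which is the ce11 sequence. The optimal set was found to be the 3053 strongest peaks of the pooled list, with identical signals. All rows were kept, including 16 optimal rows that repeat another row's interval with a different summit.

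Peaks were ranked by signal within each list, and N, the number of optimal peaks (3053), set the length of the top lists of each replicate. Overlap required at least 1 bp. Its chance level came from 1000 circular shifts of replicate 1 along each chromosome. Correlations were computed across peaks, with 100000 permutations. Gene models came from the Ensembl annotation of WBcel235, with names of mitochondrial genes from RefSeq. A gene was called bound when an optimal summit lay within 1 kb of any annotated 5′ end, over 19973 nuclear protein-coding genes, so genes that share a promoter are bound together. Each gene list and each family of genes with a shared symbol prefix was tested with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment over the 27 lists or the 175 families. The lists needed at least 5 and the families at least 10 members. Of 397 symbols entered by hand, 5 were not found in the annotation and were left out. Summit classes were compared with 1000 circular shifts (two-sided permutation p), and chromosomes with their share of genes (exact binomial test). Motifs were sought on both strands in 101-bp windows centred on the summit and 500 bp to each side, and tested with an exact two-sided sign test against 1 flank per peak drawn with a fixed seed. All 6-base words, with reverse complements merged, were tested with Fisher's exact test against both flanks. The 19 mitochondrial peaks were left out of tests on genes, locations and motifs. Shares carry 95% exact (Clopper-Pearson) intervals, which cover counting error over peaks or genes only. Peaks and genes are not independent replicates. Values for each replicate alone came from its top N peaks and are given as mean ± SD (n = 2).

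Most genes named in the text follow a rule fixed before the data were examined, as were the lists, motifs, tests and most alternatives. It takes tbx-2 and unc-119, the gene with the nearest 5′ end to each of the 20 strongest optimal peaks, up to 4 strongest bound members of each list that passes, the pharynx genes pha-4, ceh-22, myo-2 and D2096.6, and up to 3 strongest bound members of each passing family. Genes that contain a named summit or lie in the run of peaks at tbx-2 (M01F1.8, sax-2 and Y54H5A.2) are named outside this rule. The text names members only for some of the families with the lowest p, a narrowing chosen after the results were seen. The alternatives were other overlap rules, stronger peaks only, other windows and assignments, gene sets matched on upstream distance (10000 draws in 10 bins), shuffled windows, the ce10 lists and each replicate alone; leaving out peaks with a general promoter element was added after the data were seen. The overlap, list and motif steps were tested on simulated data: a planted overlap of 60% was recovered as 60.9% over 3000 peaks, and a motif added to 10% of windows was recovered in 9.93%. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.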

Results

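Binding of TBX-2 was mapped in late embryos of C. elegans, a stage at which organs such as the pharynx, the worm's feeding tube, take shape. TBX-2 is a T-box transcription factor known to be needed for the anterior pharyngeal muscles. The relaxed lists held 23800 peaks for replicate 1, 23216 for replicate 2 and 25747 for the pooled data, and the optimal set held 3053 peaks with a median width of 436 bp. Of these, 3034 lay on nuclear chromosomes and 19 on the mitochondrial genome. The optimal peaks took 11.9% of the pooled list and had signals from 81.6 to 2535.7, a value assigned by the authors' peak caller. The question the files address is where in the genome, and near which genes, tagged TBX-2 was found.

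The replicates placed their strongest peaks at the same sites. Of the 3053 strongest peaks of replicate 1, 77.3% overlapped one of the 3053 strongest of replicate 2 (95% interval 75.7 to 78.7), and 77.1% did in the reverse direction. Circularly shifted peaks overlapped in 2.96% ± 0.292 (SD over 1000 shifts), and the permutation p was 0.001, the smallest these shifts can give (one-sided). The optimal peaks were in the top list of each replicate in 87.4% ± 2.08 of cases (SD, n = 2): 2713 in replicate 1 and 2623 in replicate 2. In all, 2330 optimal peaks were in both top lists, 676 in 1 only and 47 in neither. These shares, and the correlation that follows, describe the optimal set and do not test agreement. Its peaks are the strongest by signal in the data pooled from the same replicates, and are labelled as thresholded on irreproducibility. Across the 3048 optimal peaks found in both relaxed lists, the signals of the replicates were correlated, with Spearman's rho of 0.761 and Pearson's r of 0.814 on the log2 scale. Among the weakest 3053 pooled peaks, 510 overlapped a peak in both lists, with rho of 0.523 and r of 0.735. Each was given the strongest replicate peak that it overlapped, which can be a stronger neighbour. These 2 values therefore do not measure how well weak peaks reproduce. Each permutation p was 1e-05, the smallest that 100000 permutations can give; peaks are the units here and are not independent replicates.

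**Figure D1:**
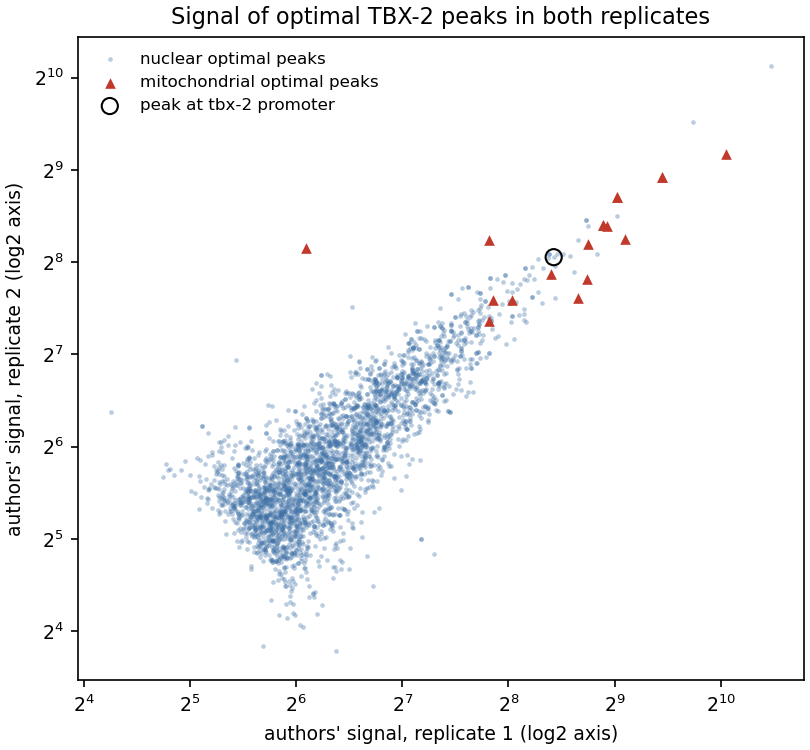
Authors' signal of each optimal peak in replicate 1 (horizontal, log2 axis) and replicate 2 (vertical, log2 axis), for the 3048 peaks found in both lists; blue points are nuclear peaks, red triangles mitochondrial ones and the circle the peak at the tbx-2 promoter. Signals rise together, with Spearman's rho of 0.761, and the mitochondrial peaks lie among the strongest.

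The 20 strongest optimal peaks included promoters of nuclear genes, tbx-2 among them, and mitochondrial DNA; those nearest to nas-30, W03C9.1 and F55C5.17 lay outside promoters. The highest signal, 2535.7, was at chromosome III 8043714 to 8044214 (ce11), with its summit at -530 bp from the 5′ end of K12H4.5 (negative distances are upstream), and this peak ranked 1 in both replicates. The next nuclear peak (rank 3, signal 1588, chromosome III 3499792 to 3500278) had M01F1.9 as its nearest gene, at -974 bp, and its summit lay inside the neighbouring M01F1.8. Peaks within 600 bp upstream of tasp-1 (a taspase), eel-1 (a HECT ubiquitin ligase), rpl-3 (a large-subunit ribosomal protein), ears-2 (a mitochondrial glutamyl-tRNA synthetase), vps-51 (a vesicle tethering subunit) and chaf-2 (a chromatin assembly factor subunit) ranked 6, 10, 12, 13, 15 and 18. The peak at vps-51 also lies at -224 bp from lin-35, the retinoblastoma homologue on the opposite strand. The peaks nearest to W03C9.1 (rank 16) and F55C5.17 (rank 17) had small nucleolar RNA genes within 250 bp, and that nearest to nas-30, an astacin protease, lay at -4966 bp. Of the 20 strongest peaks 8 were mitochondrial, and their nearest 5′ ends were those of ND5, COX2, ND4, COX1, CYTB and ND2; the strongest, with a signal of 1638, was centred at position 12497 inside ND5.

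The promoter of tbx-2 carried a strong peak, and 2 of the 4 pharynx genes chosen beforehand carried weaker ones. The tbx-2 peak (chromosome III 5136248 to 5136572, summit at -121 bp) had a signal of 606 and ranked 20 in the optimal set, 23 in replicate 1 and 21 in replicate 2. A peak at pha-4, the FoxA factor that specifies the pharynx, lay on chromosome V at 20752534 to 20752969, -300 bp from its 5′ end, and ranked 2783. A peak at ceh-22, an NK-2 homeobox gene of pharyngeal muscle, lay at 10672488 to 10672923 of chromosome V in coding sequence, 72 bp from a 5′ end, and ranked 1572. No optimal summit lay within 1 kb of a 5′ end of myo-2, the pharyngeal myosin, or of D2096.6. The peak at unc-119, the marker gene of the strain, was centred 4 bp from a 5′ end and ranked 2775 in the optimal set, 2434 in replicate 1 and 4484 in replicate 2. Peaks were crowded at tbx-2: 13 optimal summits lay within 5 kb of the gene, more than at any other protein-coding gene, against a median of 0. A run of 21 optimal peaks less than 5 kb apart covered chromosome III from 5120551 to 5151373, a stretch chosen after its values were seen, and it spans part of sax-2, all of tbx-2 and Y54H5A.2. The top lists of the replicates each held 20 peaks there.

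**Figure D2:**
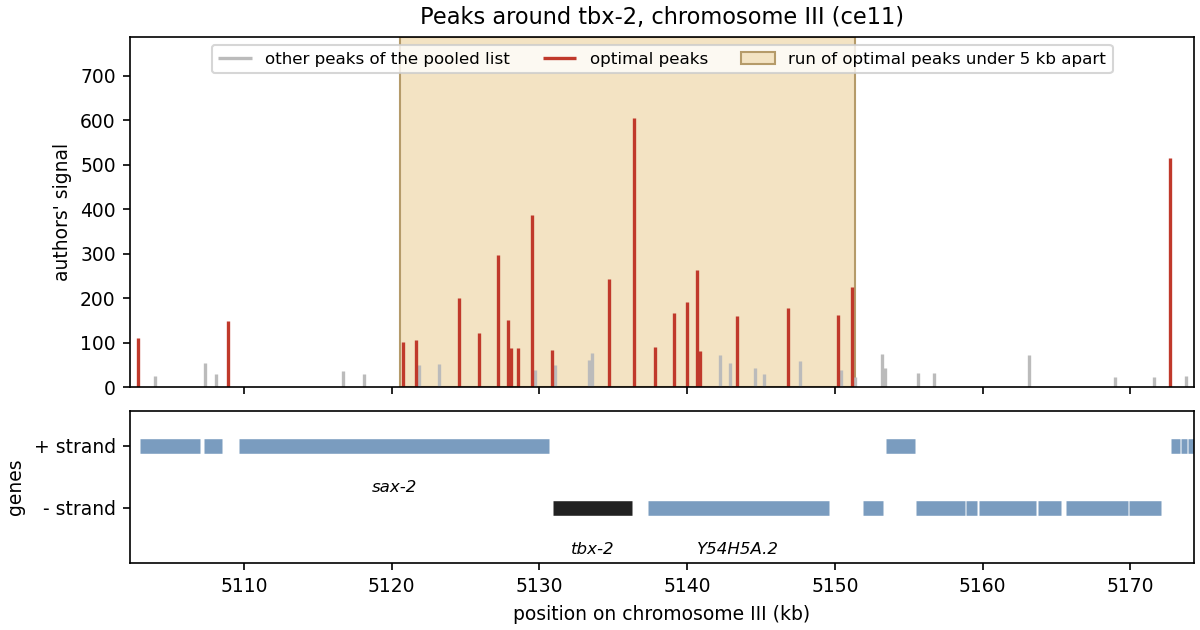
Peaks of the pooled list around tbx-2 on chromosome III in ce11 (horizontal, kb), with the authors' signal as line height in the upper panel and gene models by strand below; red lines are optimal peaks, grey lines other peaks, and shading marks the run of optimal peaks. The run holds 21 optimal peaks over 30.8 kb and its highest, with a signal of 606, stands at the tbx-2 promoter.

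TBX-2 peaks lay near 2289 of 19973 protein-coding genes (11.5%), and 6 of the 27 gene lists held more bound members than other genes did. No list from an untagged strain was available, so promoters that gather peaks in any such experiment cannot be separated from TBX-2 binding, and bound means here only that a peak lies there. Within 1 kb of any 5′ end, ribosomal protein genes stood highest: 56 of 76 were bound (73.7%, 95% interval 62.3 to 83.1, odds ratio 22.1, adjusted exact p = 1.62e-35). The replicates alone gave 69.7% ± 1.86 (SD, n = 2). With each peak given to its nearest 5′ end 34 of 76 were bound (odds ratio 5.78), below the SUMO and Groucho list (5 of 11, 5.90), body wall muscle (17 of 36, 6.36) and the genes used by all neurons (20 of 29, 15.8). The odds ratio was 11 with the 1507 stronger peaks and 11.3 with the 500 strongest, where heat shock genes stood higher (12.9). The strongest ribosomal peaks were at rpl-3 (signal 765), rpl-15 (599), rps-24 (463) and rps-28 (433). Of the heat shock and stress genes 9 of 21 were bound (odds ratio 5.81, adjusted exact p = 0.001). They were led by the chaperone genes hsp-60 (signal 385), hsp-90 (383), hsp-1 (316) and hsp-3 (314), which encode mitochondrial, cytosolic and endoplasmic reticulum chaperones.

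Genes of body wall and pharyngeal muscle, genes used by all neurons and genes of the Wnt pathway were also bound more often. In body wall muscle 13 of 36 genes had a peak (36.1%, odds ratio 4.39, adjusted exact p = 5.53e-04), among them unc-112 (kindlin, signal 298), unc-60 (cofilin, 214), unc-54 (the major myosin heavy chain, 150) and the actin gene act-2 (130.5). In pharyngeal muscle 5 of 14 genes had one (odds ratio 4.30, adjusted exact p = 0.0437), and the innexin gene inx-3 (signal 148), the actin gene act-4 (141), ceh-22 (124) and the myosin light chain gene mlc-2 (112.4) had the strongest. Of genes used by all neurons 11 of 29 were bound (odds ratio 4.74, adjusted exact p = 9.48e-04), led by syd-2 (liprin-alpha, signal 282), unc-76 (a FEZ axonal protein, 218.5), ehs-1 (an Eps15 homologue, 153) and maco-1 (macoilin, 146). Of the Wnt pathway genes 9 of 29 were bound (odds ratio 3.49, adjusted exact p = 0.0119), led by mom-1 (Porcupine, signal 276), vang-1 (Van Gogh, 179), mig-5 (Dishevelled, 163) and lin-17 (a Frizzled receptor, 146). Calls came from Fisher's exact test with adjustment over 27 lists. The pharyngeal muscle call ended with either replicate alone (4 of 14 bound in each, adjusted exact p of 0.117 and 0.146); the heat shock call ended when each peak was given to its nearest 5′ end (0.0728), the Wnt call within 500 bp (0.199), and the body wall muscle and Wnt calls among the 1507 stronger peaks (0.217 and 0.137). The pharyngeal muscle call also ended among those (adjusted exact p = 0.46), within 2 kb (0.105) and with the nearest 5′ end (0.0501). With the 500 strongest peaks the calls for all 4 of these lists ended (adjusted exact p of 0.511 for the genes of all neurons and 1 for the others).

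Peaks were rare at chemoreceptor, F-box, C-type lectin and collagen genes. Only 13 of 1364 chemoreceptor genes were bound (0.953%, odds ratio 0.0691, adjusted exact p = 4.34e-54), with the strongest peaks at sre-23 (signal 539), sre-1 (322), sri-5 (208) and srh-89 (204). F-box genes were bound in 9 of 327 cases (odds ratio 0.216, adjusted exact p = 1.05e-07), including fbxb-85, fbxc-44, fbxl-2 and fbxl-1 (odds ratio 0.351 with replicate 1 alone), and C-type lectins in 6 of 240 (odds ratio 0.196, adjusted exact p = 4.04e-06), including clec-53, clec-126, clec-140 and clec-104. Collagens were bound in 6 of 156 cases (odds ratio 0.307, adjusted exact p = 0.0047), with peaks at col-85, col-71, col-2 and col-185; this call ended with replicate 1 alone (9 of 156, odds ratio 0.484, adjusted exact p = 0.0796), among the stronger peaks (0.234) and with the 500 strongest (1). The other 17 lists did not pass. They include regulators of the pharynx (6 of 20 bound, tbx-2 itself among them, adjusted exact p = 0.0518), histones (15 of 72, 0.0528), the TGF-beta pathway (6 of 21, 0.0556) and the Notch pathway (6 of 24, 0.0952). Nuclear hormone receptors (21 of 269, 0.119), intestinal genes (0 of 24, which allows a share of up to 14.2%, 0.174), the SUMO and Groucho genes (3 of 11, 0.195) and the Hox genes (2 of 6, 0.216) did not pass either. The same holds for neuronal regulators (2 of 45, 0.233), germline genes (2 of 40, 0.426), the T-box family (1 of 22, tbx-2 itself, 0.649), ceh homeobox genes (8 of 63, 0.85), epidermal products (2 of 28, 0.86) and innexins (3 of 25, 0.86). Pharyngeal gland genes (1 of 9), regulators of the seam and hypodermis (1 of 16) and hlh genes (2 of 25) each had an adjusted exact p of 1. With replicate 2 alone 3 of 21 TGF-beta genes (odds ratio 1.305 against 3.10) and 0 of 6 Hox genes were bound, and with replicate 1 alone 1 of 11 SUMO and Groucho genes and 1 of 6 Hox genes. With replicate 2 alone the pharynx regulators passed as higher (adjusted exact p = 0.0491) and nuclear hormone receptors as lower (0.0405), and with replicate 1 alone histones passed as higher (0.0243). The 6 pharynx regulators bound with replicate 2 alone include tbx-2, the tagged gene, and the list was not tested without it. Histones also passed as higher within 500 bp (adjusted exact p = 0.0288), within 2 kb (0.0229) and among the stronger peaks (0.0122). Their odds ratio of 2.04 fell to 1.01 with the nearest 5′ end (9 of 72, adjusted exact p = 1), and to 1.24 against gene sets matched on upstream distance (0.707) and 1.12 without peaks holding a general promoter element (0.763), the last an alternative chosen after seeing the data. The Notch list passed as higher within 500 bp (adjusted exact p = 0.0366), and the TGF-beta list (0.0268) and the SUMO and Groucho list (0.0423) within 2 kb. With the nearest 5′ end all 3 passed (adjusted exact p of 0.0042, 0.0015 and 0.01735). Intestinal genes (adjusted exact p = 0.0467) and nuclear hormone receptors (0.005) passed as lower within 2 kb.

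**Figure D3:**
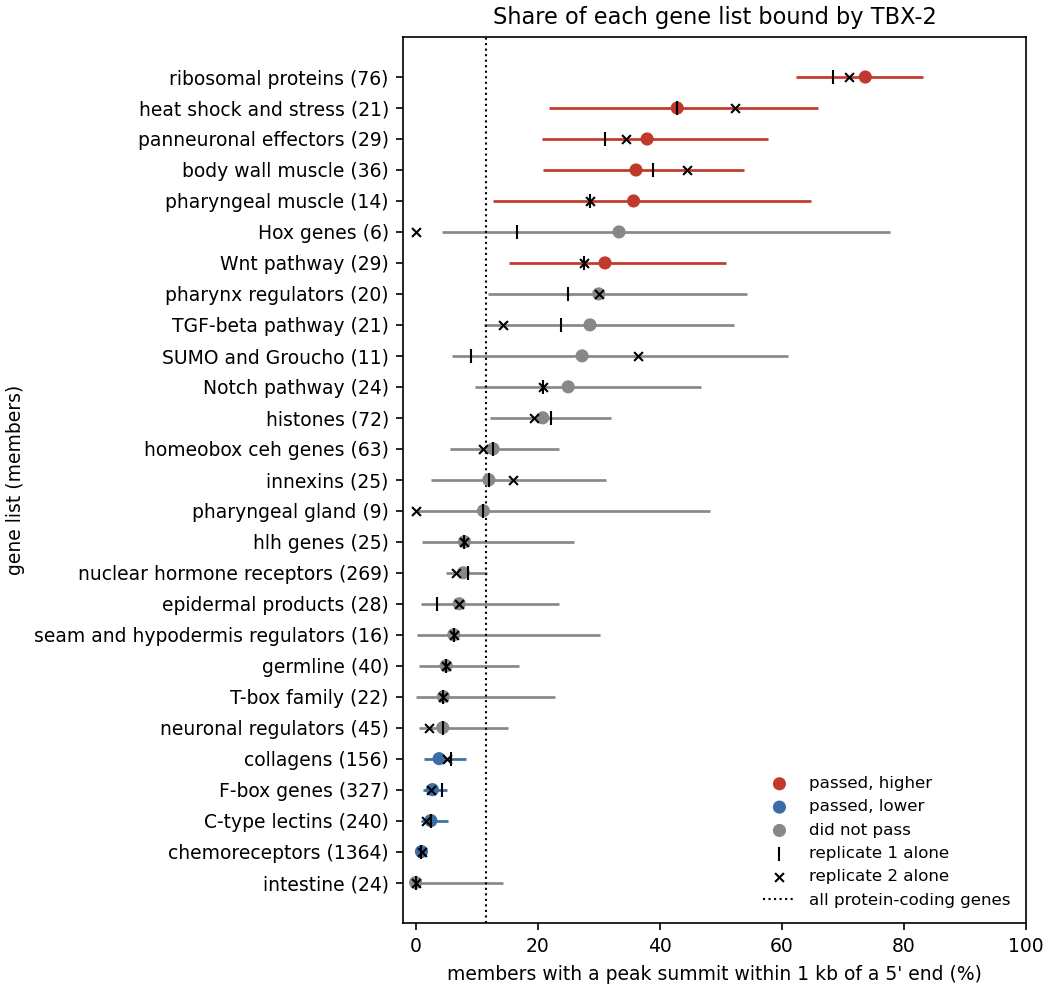
Share of each gene list (vertical, with its number of members) that had an optimal summit within 1 kb of a 5′ end (horizontal, %); dots and lines give the share and its 95% exact interval, coloured by the Fisher test, black marks the top list of each replicate alone, and the dotted line all protein-coding genes (11.5%). Ribosomal proteins reach 73.7% and chemoreceptors 0.953%.

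Among families of genes with a shared symbol prefix, 21 of 175 were bound more often and 18 less often than other genes. The large- and small-subunit ribosomal families rpl and rps led, with 34 of 47 and 23 of 31 members bound (adjusted exact p of 4.49e-20 and 5.73e-14), and rpl-35 and rps-12 had signals of 433 and 303. The lin family, named for cell lineage mutants and mixed in function, had 24 of 47 bound (odds ratio 8.14, adjusted exact p = 1.57e-09; 18 of 47 and 4.89 with replicate 2 alone), with the strongest peaks at lin-35 (signal 655), lin-66 (350) and lin-54 (307). Of these, the lin-54 peak lay nearer to a ribosomal protein gene (-9 bp against -384 bp). The lin-35 peak lay nearer to vps-51 (-194 bp against -224 bp). The unc family, named for movement defects, had 26 of 94 bound (odds ratio 2.98, adjusted exact p = 1.94e-04), with peaks at unc-115 (signal 286) and unc-85 (275). Vesicle sorting genes (vps, 14 of 31, odds ratio 6.40, adjusted exact p = 5.97e-05) included vps-51, vps-32.1 and vps-25. Translation initiation factors (eif, 12 of 25, odds ratio 7.16, adjusted exact p = 1.20e-04) included eif-3.E (signal 415), eif-3.I (414) and eif-3.B (301.5), and secretion genes (sec, 10 of 19, odds ratio 8.62, adjusted exact p = 1.94e-04) included sec-15, sec-61.G and sec-61.B. Among the less bound, the chemoreceptor family str had 1 of 193 members bound (str-12) and srh 4 of 220, while srw (0 of 109, upper limit 3.33%), srx (upper limit 3.59%) and the cytochrome P450 family cyp (0 of 74, upper limit 4.86%) had none. Among the 1507 stronger peaks 13 families passed as higher and 6 as lower.

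Most summits lay near the start of a protein-coding gene, on chromosomes I, III and X more often than on the others. Of the 3034 nuclear summits 61.3% were within 1 kb of a 5′ end (95% interval 59.6 to 63.1) against 40.4% ± 0.996 in shifted peaks (SD), and the replicates alone gave 60.6% ± 0.564 (SD, n = 2). Promoters, the 1 kb upstream, held 55.6% of summits against 21.9% by chance, coding sequence 1.05% against 20.96%, introns 17.01% against 28.9% and 3′ UTRs 0.231% against 2.42%. With replicate 1 alone coding sequence held 1.65% and 3′ UTRs 0.4285%, and with replicate 2 alone 3′ UTRs held 0.4288%. Each of these had a permutation p of 0.002, the smallest that 1000 two-sided shifts can give. The 5′ UTRs held 1.22% (permutation p = 0.464) and remaining sequence 24.9% against 24.7% (p = 0.903). The weakest 3053 peaks of the pooled list were within 1 kb of a 5′ end in 41.1%, against 41.03% by chance. The X chromosome held 20.5% of nuclear peaks against 13.7% of genes (ratio 1.497, adjusted exact p = 2.69e-24), chromosome I 19.5% against 14.4% (ratio 1.35, adjusted exact p = 5.07e-14) and chromosome III 17.4% against 13.2% (ratio 1.31, adjusted exact p = 1.21e-10). Chromosome V, home to many chemoreceptor genes, held 12.5% against 25% (ratio 0.498, adjusted exact p = 3.68e-65), and chromosomes II (ratio 0.886, adjusted exact p = 0.0044) and IV (0.909, 0.0258) were also lower. These are exact binomial tests. Against chromosome length the X ratio was 1.158, below I (1.296) and III (1.264), and II no longer differed (ratio 1.004, adjusted exact p = 0.920); IV did not differ with replicate 2 alone (adjusted exact p = 0.178).

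Summits were rich in the GA repeat, the CTGCGTCT element and the GC-box, called general promoter elements here. Nuclear summits without these elements lay within 1 kb of a 5′ end in 63.0% of cases, against 61.3% of all. The elements therefore did not mark the summits near gene starts. Few summits held the T-box site GGTGTGA. The T-box site GGTGTGA lay within 50 bp of 40 of 3034 summits (1.32%, 95% interval 0.944 to 1.79) against 0.544% in the flanks (ratio 2.42, adjusted exact p = 0.005 by the exact sign test over 15 motifs), and the replicates alone gave 1.47% ± 0.116 (SD, n = 2). The shorter core GTGTGA lay at 8.73% against 3.82% (ratio 2.28, adjusted exact p = 5.53e-13), and the longer AGGTGTGA at 0.527% against 0.0989% (ratio 5.33, adjusted exact p = 0.0177; ratio 2.73 with replicate 2 alone). A scrambled pattern with the same bases as the site GGTGTGA, AGTGTGG, was at 1.98% against 0.577% (ratio 3.43, adjusted exact p = 2.99e-06), while the scrambled patterns GTGGATG and GAGTTGG had ratios of 1.33 and 1.39 (adjusted exact p of 0.497 and 0.0834). The GA repeat GAGAGAG lay at 15.3% of summits against 1.27% (456 peaks at the summit only, 26 in the drawn flank only), the CTGCGTCT element at 10.3% against 0.527% (adjusted exact p = 3.85e-75) and the GC-box GGGCGG at 7.81% against 1.55% (5.90e-37). The E-box CAGCTG was also higher (3.23% against 2.08%, adjusted exact p = 0.0114), the CRE element TGACGTCA was at 1.19% against 0.643% (0.0551) and forkhead sites at 24.4% against 26.9% (0.126). GATA sites (12.8% against 19.7%, adjusted exact p = 1.60e-11), the homeodomain site TAATTA (1.65% against 5.22%, 1.49e-14) and the AP-1 site (0.659% against 1.02%, 0.0452) were lower at summits. Against windows shuffled with their dinucleotide counts kept, the site GGTGTGA was no more frequent (1.32% against 1.65%, adjusted exact p = 0.422), and neither was it among the 1507 stronger peaks against their flanks (ratio 1.65, adjusted exact p = 0.467). With replicate 2 alone the E-box and AP-1 calls ended (adjusted exact p of 0.0768 and 0.109) and forkhead sites passed as lower (0.0217), and with replicate 1 alone the AP-1 call ended (0.699). The E-box call also ended among the stronger peaks (adjusted exact p = 0.104) and within 25 bp (0.109), the AP-1 call among the stronger peaks (0.0543) and within 100 bp (0.248), and the AGGTGTGA call among the stronger peaks (0.544). Without peaks holding a general promoter element the calls for GGTGTGA (ratio 1.92, adjusted exact p = 0.0526), AP-1 (ratio 0.605, 0.0912) and AGGTGTGA (ratio 3, 0.0892) ended and CRE sites passed as higher (0.0278), and GAGTTGG passed as higher within 100 bp (0.0264). The shorter core stayed above shuffled windows (8.73% against 6.79%, adjusted exact p = 0.0089). Against those windows CRE sites (ratio 9, adjusted exact p = 5.57e-07) and forkhead sites (ratio 1.44, 4.36e-13) passed as higher. The ratio of the GA repeat fell from 12.03 to 2.76 (adjusted exact p = 8.37e-47) and that of the GC-box from 5.04 to 1.78 (1.89e-08). That of the CTGCGTCT element rose from 19.4 to 28.3 (adjusted exact p = 3.91e-77). AGTGTGG (ratio 1.46, adjusted exact p = 0.105), AGGTGTGA (0.842, 0.788) and TAATTA (1.19, 0.507) no longer passed.

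**Figure D4:**
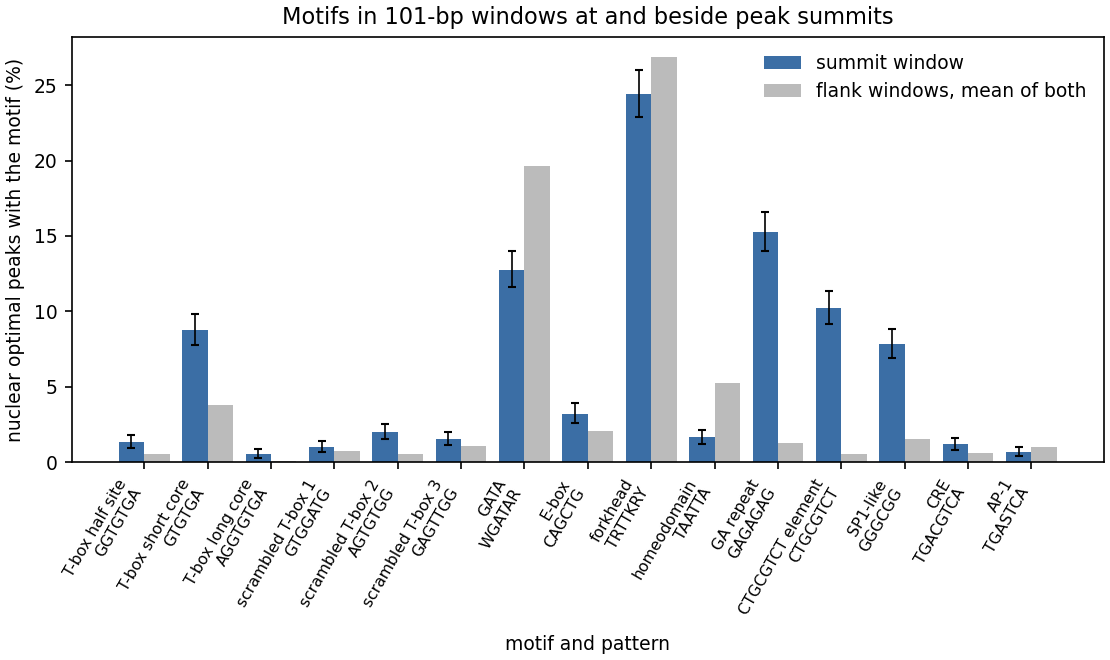
Share of the 3034 nuclear optimal peaks (vertical, %) with each motif within 50 bp of the summit (blue, with 95% exact intervals) and in the windows 500 bp to each side (grey, mean of both). GA repeats reach 15.3% at summits against 1.27% in flanks, and the T-box site GGTGTGA 1.32% against 0.544%.

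In the search of all 2080 words of 6 bases, 856 were more frequent at summits and 647 less frequent (adjusted Fisher tests), and GC content was 49.1% at summits against 35.5% and 35.6% in the left and right flanks. The leading word was GAGAGA, at 31.0% of summits against 5.06% in flanks, and CA repeats also ranked high (CACACA, 18.1% against 4.09%, rank 10). Of the words within the T-box site, GGTGTG ranked 266 by p (6.82% against 2.31%) and the core GTGTGA ranked 330. The T-box site GGTGTGA was not more frequent at stronger peaks: it lay at 0.922% of the 759 strongest and 2.11% of the 758 weakest peaks (Spearman's rho -0.0350 between signal and presence, permutation p = 0.0547, two-sided). With replicate 1 alone this permutation p was 0.0460 (rho -0.0362), and with replicate 2 alone 0.638 (rho -0.0086).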

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

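The test of how much of the mitochondrial genome the peaks cover was chosen after the peaks had been seen, and how to read the core test was settled after its value was seen. The 19 optimal peaks on the mitochondrial genome lie outside every test on nuclear genes, and no untagged control sample was analysed here. They are among the strongest in both replicates, with 9 of the 20 strongest peaks of each replicate list and 8 of the 20 strongest optimal ones, and a median signal of 556 against 125.9 over the whole optimal set. They cover 47.3% of the 13794 bp of mitochondrial DNA, while nuclear peaks cover 1.17% of the nuclear genome. This share follows from the number and width of the peaks that prompted the test, so it does not decide on a high copy number of mitochondrial DNA as a technical source. That source stays open, and the authors called the peaks against a control library, which was not available here. The core GTGTGA lay within 50 bp of 0 of the 19 summits, against 0.696% of random mitochondrial positions (permutation p = 1, one-sided), but at the 8.73% of nuclear summits a count of 0 would still have an exact probability of 0.176. As 0 of the 19 summits had it, this exact core within 50 bp is argued against as the source of the mitochondrial peaks. Looser T-box sites were not sought there and stay open. With 1 group in the design, no biological explanation could be tested by comparing groups.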

How the results depend on the processing

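Removing peaks with a general promoter element, and leaving out replicates in the search of 6-base words, were chosen after seeing the data. No paired analysis was possible because the 2 replicates form a single group. Overlap between replicates moved to 70.9% with summits within 100 bp, 79% in the top 500 peaks and 80.9% in the top 1526. With summits within 100 bp, optimal peaks in the top lists moved to 85.9% in replicate 1 and 82.7% in replicate 2. With the 500 strongest peaks 2 lists passed as higher, and the pharyngeal muscle odds ratio turned to 0; with the 1507 stronger peaks, 13 families passed as higher and 6 as lower. Fewer peaks bind fewer genes by construction. The enrichment of the T-box site GGTGTGA fell to 1.65 in the stronger peaks and 1.92 without peaks holding a general promoter element, and no longer passed (adjusted exact p of 0.467 and 0.0526). Against shuffled windows it turned to 0.8, that of the long core to 0.842, of homeodomain sites to 1.19 and of forkhead sites to 1.44, while that of CRE sites rose to 9, where the control keeps the composition of the summits. The relation of that site to peak strength ran from -0.0362 to -0.0086 over the replicates alone. Summits outside promoters and genes, not different from chance in the main setting, lay below it at 21.2% in the stronger peaks, 17.6% in the 500 strongest, 16.25% with a 2 kb window and 22.6% without general promoter elements, and above it at 33.06% with a 500 bp window; chromosome II turned to 1.004 times its share of length. For these other changes the cause was not tested. Over the other settings lists passing as higher ran from 4 to 8 and as lower from 3 to 6, and chromosomes that differed from 5 to 6. Among single lists, motifs, chromosomes and classes 29 alternatives lost a call and 19 gained one with no change of direction, and 9 changed direction. Read depth is unknown, so its effect on weak peaks cannot be given.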

Other observations

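The test against scrambled words was chosen after its result was seen, as were the counts by product word and by type of RNA gene and the run of peaks at tbx-2 with its content. Peaks were frequent at genes of short structural RNAs, a class outside the gene lists. Of the 3034 nuclear optimal summits, 9.10% lay within 250 bp of a tRNA, snRNA, snoRNA or rRNA gene, against 0.646% in circularly shifted peaks (permutation p = 0.002, the smallest 1000 two-sided shifts can give) and 9.05% ± 0.392 in the replicates alone (SD, n = 2). By type, 177 summits were near tRNA genes (17.2 times the shifted share), 80 near snoRNA genes (12 times) and 20 near snRNA genes (9.26 times), while 0 were near any of the 20 rRNA genes (permutation p = 1). In all 185 of 612 tRNA genes (30.2%) and 79 of 346 snoRNA genes (22.8%) had such a peak. The peaks at tRNA genes held a GA repeat, CTGCGTCT element or GC-box in 12.4% of cases and the core GTGTGA in 5.08%, against 30.5% and 9.10% in peaks away from these genes.

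Product names were also searched for single words. Of 201 words carried by at least 30 genes, 44 were more frequent and 41 less frequent among bound genes. Genes with "subunit" in their name were bound in 278 of 896 cases (odds ratio 3.82), "mitochondrial" in 85 of 303 (3.09), "ubiquitin" in 20 of 59 (3.99), "proteasome" in 13 of 41 (3.60) and "serpentine" in 11 of 1085 (0.0747), the last being chemoreceptors. General promoter elements were held by 29.0% of nuclear optimal summits against 5.99% of the weakest 3053. Without those peaks ribosomal protein genes were still bound more often (odds ratio 19.4 against 22.1). Exact copies of the elements within 50 bp of a summit therefore do not account for that list. Copies farther out were not removed: within 100 bp the GA repeat lay at 25.6% of nuclear summits, against 15.3% within 50 bp. The heat shock list fell from an odds ratio of 5.81 to 3.26 and missed the threshold, and the pharyngeal muscle list missed it with 4 of 14 bound and a similar odds ratio (4.175 against 4.30); the adjusted exact p was 0.0781 for each.

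The T-box site GGTGTGA was no more frequent than in shuffled windows of the same composition (1.32% against 1.65%, exact sign test p = 0.337). Base composition may therefore account for the enrichment of this site. The scrambled words were divided. AGTGTGG, which shares the run GTGTG with the site, reached a ratio of 3.43 over the flanks against 2.42. GTGGATG and GAGTTGG stayed below the site, at 1.33 and 1.39. For the shorter core, general promoter elements within 50 bp of the summit are argued against as the whole cause of its excess over flanks. Among peaks without them it lay at 7.70% of summits against 3.83% in flanks (exact sign test p = 6.25e-07). CA repeats, present at 22.6% of summits, are argued against as the whole cause of that excess. Among 2205 peaks free of them the core lay at 5.03% against 2.27% (exact sign test p = 8.93e-07), a test made once the repeats had been seen. Both comparisons used flanks, whose GC content was lower (35.5% and 35.6% against 49.1%), so neither separates the core from base composition. The core lay at 21.7% of the 686 summits with a repeat, so most of the summits with the core held such a repeat. Base composition may account for part of the excess of the core: its ratio fell from 2.28 over flanks to 1.29 over shuffled windows. What stays open is whether the core marks direct contact, as no biological explanation was tested with 1 group.

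The 30.8 kb run at tbx-2 held 21 optimal peaks, while windows of that length elsewhere held 0.927 on average and at most 14. Strong promoter binding alone is argued against: of 12 other genes with as strong a promoter peak, 0% had as many peaks within 5 kb, the highest having 3. Between 5 and 15 kb outside the gene there were 8 optimal peaks, above the upper limit of 3 for the middle 95% of all genes. Extra copies of the locus carried by the transgene may account for the run. These 8 peaks belong to the run itself, so their count does not tell extra copies from a spread of TBX-2 there. The authors called peaks against a control library, which was not available here. The part of the locus in the transgene is not given in the sources used here. At unc-119, the marker of the strain, taken to lie on the transgene as well, 1 peak lay within 5 kb. Between 5 and 15 kb outside that gene there were 0 optimal peaks. How much of the unc-119 locus the transgene carries is not given either, so these counts do not decide on extra copies. The run's peaks were near a 5′ end in 14.3% of cases (3 of 21, against 61.3% of all) and held GTGTGA in 28.6% (6 of 21, 95% interval 11.3 to 52.2, against 8.73%). As the run was chosen after its values were seen and the core was not separated from base composition, these shares do not decide. A real concentration of TBX-2 at its own gene stays open.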
